A study of Homo sapiens with 18 samples.

How the data were processed

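The series holds 18 arrays of OCI-AML3 cells in 3 groups of 6, treated for 24 h with DMSO, with 2 µM RG7112 or with 500 nM HDM201, and each compound was given at a single dose and time. The cells grew in RPMI medium with fetal calf serum, total RNA was extracted with a miRNeasy kit, and biotin-labelled cDNA was made with a WT Pico kit, per the labels. The authors deposited log2 values made with the oligo package and its RMA method, which corrects background, normalizes quantiles across arrays and summarises probe sets, per the submitters' processing notes. Versions of these tools and the genome build are not given in the sources used here, so no coordinates are reported.

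The table has 21448 probes. A reference table gave 17709 of them exactly 1 gene symbol, 0 several and 3739 none here, and the 17709 probes cover 17687 distinct symbols. Probes without a symbol stay in the counts of changed probes and in the adjustment for multiple testing, but not in the gene lists. For 20 symbols with more than 1 probe the lists use the probe with the highest mean. Some genes are not reported here. All 18 columns of the table were used, and every array was kept in each test. Array medians of 6.44 to 6.57, lowest signals of 2.66 to 2.85 and correlations between arrays of 0.952 to 0.996 over probes describe the signal.

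Samples were grouped by their labels. The labels call the replicates biological and do not say how cultures were separated or whether a replicate number marks a shared day. The tests, the alternatives, the members of the gene lists and the rule for naming genes were fixed before the data were examined.

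Each probe was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 18 arrays and the default empirical Bayes step. The contrasts were RG7112 minus DMSO, HDM201 minus DMSO and HDM201 minus RG7112. A probe is said to have changed when its p, adjusted by Benjamini and Hochberg over all 21448 probes, lay under 0.05, and "rose", "fell" and "passed" are used for such probes only. Standard errors and 95% intervals come from the same model. A further count takes the changed probes with a difference of at least 1 on the log2 scale, which is 2-fold.

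The 22 gene lists cover p53 targets, G1/S and DNA replication, G2/M and mitosis, homologous recombination and the Fanconi pathway, MHC class I and class II presentation, death receptor signalling, the BCL2 family, ligands of T and NK cells, interferon response, NF-kB and inflammatory cytokines, monocyte, granule and HOX programmes, MYC and ribosome biogenesis, cholesterol synthesis, glycolysis, the integrated stress response, heat shock, and markers of lymphocytes, of erythroid cells and megakaryocytes, and of fibroblasts and epithelia. They were written from general knowledge of these pathways and hold 467 distinct genes, of which 413 were measured. Lists share up to 2 measured genes, as the p53 list does with the death receptor list and with the BCL2 family. Each list was tested with limma's camera at a preset correlation of 0.01 and adjusted over the 22 lists. The test was repeated with the correlation estimated from the data, which is called an estimated correlation in the text. Beside it stand the numbers of members that rose, fell or did not pass, over all probes and when adjusted over the list alone, and the mean of the members' changes. For HDM201 against RG7112 the mean of each list per array was compared by an exact permutation test, two-sided, over 924 permutations, with 95% intervals from inverting the test. That test can give no p below 0.00217.

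The text names genes by a rule. It takes a fixed set of 20, of which 16 have a named probe here. It adds, for each comparison with DMSO, the 8 highest and 8 lowest changes among changed probes whose arrays do not overlap between the groups (6 and 6 between the compounds). From each list it takes up to 4 changed members with the largest differences and the member with the largest difference that did not pass. Genes outside this rule are marked as chosen after their values were seen.

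The relation of the compounds was described by the correlation, the covariance and the total least squares slope of their changes over all probes, with a jackknife over arrays for the slope. Both changes use the same DMSO arrays. The values that sharing alone can produce were taken from 100 simulated pairs of unchanged groups against shared controls. In 20 splits of the DMSO arrays each compound had separate controls, which gives the relation with the sharing removed.

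The alternatives were a prior that follows the signal and is robust to outliers, array weights, leaving out the dimmest probes in 2 steps, probes with 1 symbol only, subtraction of each array's median, a further quantile normalization, only the 12 arrays compared, the replicate number as a block, and leaving out each array in turn. For the lists they also included the estimated correlation and the mean over all probes of a symbol. After the arrays had been seen to differ between replicates 1 to 3 and 4 to 6, further settings were added: the set as a block, the set as a block without the third RG7112 array, each set alone, and the estimated correlation with the set as a block. Random steps used the seed 11.

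The scripts were tested on simulated data with 21448 probes, of which 200 changed. At a change of 0.5 on the log2 scale 68.7% of them were found for RG7112 against DMSO and 73.1% for HDM201 against RG7112, at 1 97.0% and 100%, and at 2 all. Of the calls 5.35% and 4.21% were false, and a comparison with no change gave 0 calls. A simulated shift of 0.5 in 1 list was called, and no other list was. The simulated values were independent between genes and arrays and held no replicate sets. They therefore do not show how many list or probe calls are false where genes are correlated or arrays fall into sets.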

Results

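OCI-AML3 is a human acute myeloid leukaemia cell line. The cells were treated for 24 h with the solvent DMSO, with RG7112 at 2 µM or with HDM201 at 500 nM. The labels call both compounds inhibitors of MDM2, the ubiquitin ligase that keeps p53 protein low, and the title of the series concerns p53 and immunity against leukaemia after stem cell transplantation. RNA of 6 biological replicates per group was measured on 18 arrays, and the values are log2 signals of 21448 probes, of which 17709 carry 1 gene symbol. The labels do not say how the replicate cultures were separated, so the p-values measure the spread between these samples. Array medians lay between 6.44 and 6.57, and the number of arrays limits the precision. Changes are differences of group means on the log2 scale, or folds derived from them, with the standard error (SE) of the linear model and n = 6 arrays per group throughout.

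The arrays differed in ways that the treatment groups do not describe. Replicates 1 to 3 stood apart from replicates 4 to 6 in every group, and 1712 probes differed between these sets with the group means in the model. The split of numbers 1, 5 and 6 from 2, 3 and 4 gave 202 probes. Each other split of the replicate numbers into equal parts gave 0, so the 202 point to a further grouping by number. Among the DMSO arrays the mean of the p53 target list was 7.78 ± 0.07 (SD, n = 3) in replicates 1 to 3 and 7.33 ± 0.06 (SD, n = 3) in replicates 4 to 6. CDKN1A, which encodes the cell cycle inhibitor p21, was higher by 1.65 in DMSO replicates 1 to 3 than in 4 to 6 (adjusted p = 2.0e-06), and MDM2 by 0.89 (adjusted p = 1.52e-04). Changes within each set therefore stand beside the pooled values. RG7112 replicate 3 had a narrower signal range, with an interquartile range of 3.45 against 3.70 to 3.91 on the other arrays. Its mean correlation with its own group over probes was 0.972, against 0.986 to 0.988 for the other RG7112 arrays.

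The comparison of RG7112 with DMSO asks what MDM2 inhibition does to transcripts of these leukaemia cells. RG7112 raised the p53 programme: CDKN1A rose 15.6-fold (log2 change 3.97 ± 0.33 SE, adjusted p = 9.07e-08; 3.57 within replicates 1 to 3 and 4.36 within 4 to 6), and MDM2, itself a p53 target, rose 5.95-fold (2.57 ± 0.17, adjusted p = 4.95e-09; 2.32 and 2.83 within the sets). Of the 40 measured p53 target genes 37 rose, none fell and 3 did not pass, and the counts were equal when adjusted over the list alone. TP53I3 rose 9.74-fold and TP53INP1 9.33-fold, both induced by p53 under stress, and CMBL, a hydrolase, rose 15.0-fold. BAX, an executor of mitochondrial apoptosis, rose 1.94-fold (0.95 ± 0.10, adjusted p = 1.41e-06), with a signal of 11.41 on RG7112 replicate 3 and 10.99 to 11.10 on the other arrays of the group. PMAIP1, which encodes the apoptosis activator NOXA, was the member with the largest difference that did not pass (0.16 ± 0.14, adjusted p = 0.477). The mean over the list changed by 1.58 (1.61 within replicates 1 to 3 and 1.54 within 4 to 6), with adjusted p = 6.52e-41 for the list and adjusted p = 0.0485 with an estimated correlation. With the replicate sets added to that model the list gave adjusted p = 1.38e-06. MDM4, the partner of MDM2 in holding p53 down, differed by 0.31 ± 0.11 and missed the threshold (adjusted p = 0.0612). It passed when DMSO replicate 5 (adjusted p = 0.0184), RG7112 replicate 2 (0.0407) or RG7112 replicate 4 (0.0401) was left out. It also passed with a prior that follows the signal (0.0437), without the probes below the median signal (0.0378) and after a further quantile normalization (0.0405).

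The genes with the largest increase lay partly outside the p53 list. FCER1A, the alpha chain of the high-affinity IgE receptor, rose 29.9-fold (4.90 ± 0.54, adjusted p = 2.11e-06), CLCA2, a regulator of chloride conductance, 21.5-fold (4.42 ± 0.55, adjusted p = 8.46e-06), and ENPP2, the enzyme autotaxin, 16.7-fold (4.06 ± 0.25, adjusted p = 3.14e-09). DLX5, a homeobox transcription factor, rose 10.4-fold. The DMSO signals of FCER1A (3.38 to 3.82) and CLCA2 (3.23 to 3.63) lay near the bottom of the range, where the lowest signals were 2.66 to 2.85, so their folds are lower bounds. The FCER1A change was 6.00 within replicates 1 to 3 and 3.81 within 4 to 6, and that of CLCA2 5.64 and 3.21. The difference between the sets passed for both genes (adjusted p = 0.00744 and 0.0117).

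**Figure D1:**
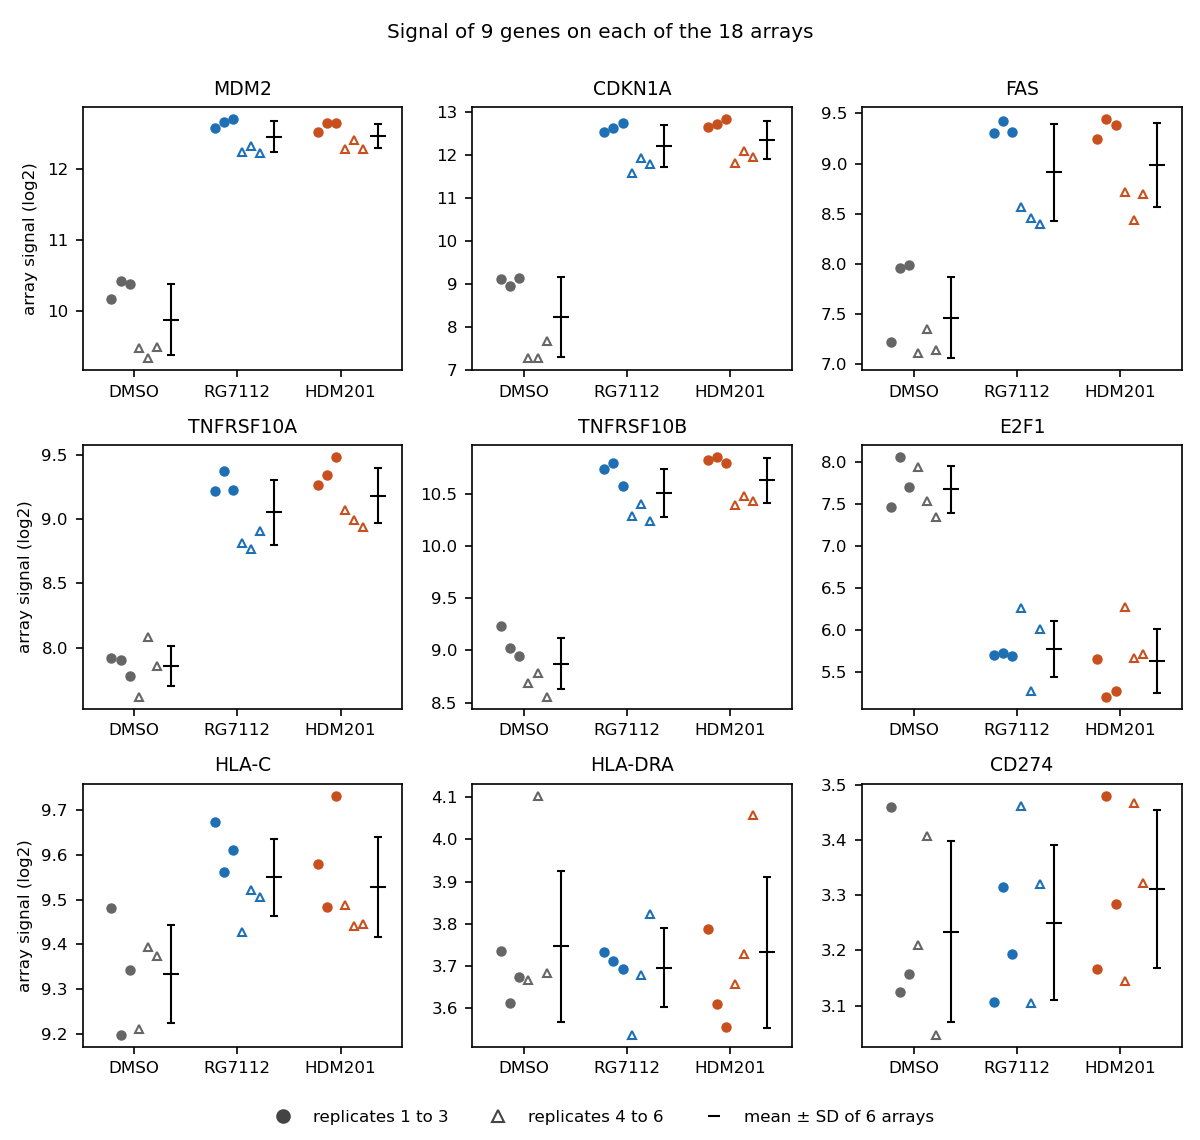
Array signal (log2) of 9 genes on each of the 18 arrays by group, with filled circles for replicates 1 to 3, open triangles for replicates 4 to 6, and a bar for the mean and SD of 6 arrays. MDM2, CDKN1A, FAS, TNFRSF10A and TNFRSF10B are higher and E2F1 is lower under both compounds, while HLA-DRA (mean 3.75 under DMSO) and CD274 (mean 3.23 under DMSO) stay near the bottom of the signal range.

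Proliferation genes fell together. All 31 measured G1/S and DNA replication genes fell, as did all 30 G2/M and mitosis genes. E2F1, a transcription factor that drives entry into S phase, fell 3.74-fold (-1.90 ± 0.17, adjusted p = 2.54e-07; -2.04 within replicates 1 to 3 and -1.76 within 4 to 6). CCNE2, a G1/S cyclin, fell 3.60-fold, GINS2, a part of the replicative helicase, 3.46-fold, and MCM10, which helps to activate it, 3.38-fold. MKI67, the proliferation marker, fell 2.24-fold (-1.16 ± 0.20, adjusted p = 2.46e-04), and DMSO replicate 3 lay below the other DMSO arrays for this gene (11.1 against 11.3 to 11.4). TTK, a kinase of the spindle checkpoint, fell 2.76-fold and KIF20A, a kinesin of cell division, 2.99-fold. The G1/S list mean was -1.29 (-1.43 and -1.15 within the sets), with adjusted p = 1.59e-40 and adjusted p = 0.0485 with an estimated correlation. With the replicate sets added to that model the G1/S list gave adjusted p = 0.0265. The G2/M list mean was -1.23 (-1.53 and -0.93 within the sets, adjusted p = 1.76e-30), and this call was lost at adjusted p = 0.0816 with an estimated correlation.

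Of the 12 measured genes of homologous recombination and the Fanconi pathway 10 fell, 1 rose and 1 did not pass, and 11 fell and 1 rose when adjusted over the list alone. EXO1, a nuclease that resects DNA ends, fell 3.15-fold (-1.65 ± 0.17, adjusted p = 8.84e-07), and RAD54L, a DNA motor protein, 2.97-fold. On average the recombination genes changed by -1.22 (-1.40 and -1.05 within the sets), with adjusted p = 1.92e-13. The list gave adjusted p = 0.0485 with an estimated correlation, and adjusted p = 0.0540 with an estimated correlation and the replicate sets in the model.

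Antigen presentation genes moved little. Of 17 measured MHC class I presentation genes 3 rose, 1 fell and 13 did not pass, with equal counts when adjusted over the list alone. TAP1, a subunit of the peptide transporter, rose 2.48-fold (1.31 ± 0.14, adjusted p = 2.02e-06; 1.53 and 1.10 within the sets), and PSMB9, a subunit of the immunoproteasome, fell 1.35-fold (-0.43 ± 0.12, adjusted p = 0.0190). HLA-G rose 1.19-fold (0.25 ± 0.07, adjusted p = 0.0198) and HLA-C, a classical class I molecule, 1.16-fold (0.22 ± 0.07, adjusted p = 0.0490). The HLA-G call was lost without DMSO replicate 2 (adjusted p = 0.0576), without DMSO replicate 6 (0.0520) and with each array's median subtracted (0.0594). Among the fits with 1 array left out, the HLA-C call held only without DMSO replicate 1, RG7112 replicate 4 or HDM201 replicate 3. It was lost when any 1 of the other 15 arrays was left out (adjusted p from 0.0551 to 0.115), and HLA-C was also lost with array weights (0.0540), with each array's median subtracted (0.134) and with only the DMSO and RG7112 arrays in the model (0.0780). B2M, the light chain of class I molecules, differed by 0.15 ± 0.07 (adjusted p = 0.181). The class I list mean was 0.14 (0.13 and 0.15 within the sets) and did not pass (adjusted p = 0.142).

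Of 16 measured MHC class II presentation genes none rose, 2 fell and 14 did not pass, and none passed when adjusted over the list alone. The genes that fell were CIITA, the transactivator of class II genes (-0.48 ± 0.16, adjusted p = 0.0444), and HLA-DMA, a chain of the peptide exchange factor (-0.59 ± 0.19, adjusted p = 0.0377). Among the fits with 1 array left out, the CIITA call held only without DMSO replicates 2 or 4, RG7112 replicates 3 or 4, or HDM201 replicates 1 or 3. It was lost when any 1 of the other 12 arrays was left out (adjusted p from 0.0504 to 0.110). The CIITA call was also lost with only the DMSO and RG7112 arrays in the model (0.0901). That of HLA-DMA was lost without DMSO replicates 1, 2, 3 or 5 or RG7112 replicates 3, 4 or 5 (adjusted p from 0.0511 to 0.0872), with array weights (0.0569) and with only the DMSO and RG7112 arrays in the model (0.0512). HLA-DRA, a class II alpha chain, had a mean of 3.75 under DMSO, where the lowest signals on the arrays were 2.66 to 2.85, and differed by -0.05 ± 0.09 (adjusted p = 0.766), with DMSO replicate 5 at 4.10 and the other DMSO arrays at 3.61 to 3.74. CD74, the invariant chain, differed by -0.25 ± 0.18 (adjusted p = 0.375). Over the class II list the mean was -0.03 (-0.05 and -0.01 within the sets), the median 0.05 and the test pointed up without passing (adjusted p = 0.779).

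Receptors of extrinsic apoptosis rose. TNFRSF10A and TNFRSF10B, the death receptors for TRAIL, rose 2.29-fold (1.19 ± 0.12, adjusted p = 5.26e-07; 1.41 and 0.98 within the sets) and 3.10-fold (1.63 ± 0.13, adjusted p = 3.93e-08; 1.63 and 1.64 within the sets). FAS, the receptor for FAS ligand, rose 2.73-fold (1.45 ± 0.22, adjusted p = 8.67e-05; 1.62 and 1.27 within the sets), and TNFRSF10D, a decoy receptor for TRAIL, 2.00-fold. Of 13 measured death receptor pathway genes 6 rose, none fell and 7 did not pass, with equal counts when adjusted over the list alone, and 2 of the 13 are also on the p53 list. On average the death receptor list changed by 0.50 (0.54 and 0.47 within the sets, adjusted p = 1.40e-04), a call lost at adjusted p = 0.0816 with an estimated correlation. On this list DMSO replicate 4 lay below the other DMSO arrays (7.86 against 8.03 to 8.11). In the BCL2 family 5 of 16 measured genes rose, 1 fell and 10 did not pass, with 7 up and 1 down when adjusted over the list alone. BCL2A1, an inhibitor of apoptosis, rose by 1.38 on the log2 scale and BAK1, an executor like BAX, 1.57-fold. The family mean was 0.22 (0.26 and 0.18 within the sets, adjusted p = 0.0309; adjusted p = 0.357 with an estimated correlation). That call was lost without RG7112 replicate 2 (adjusted p = 0.0554), without RG7112 replicate 5 (0.0624) and within replicates 4 to 6 alone (0.0781).

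**Figure D2:**
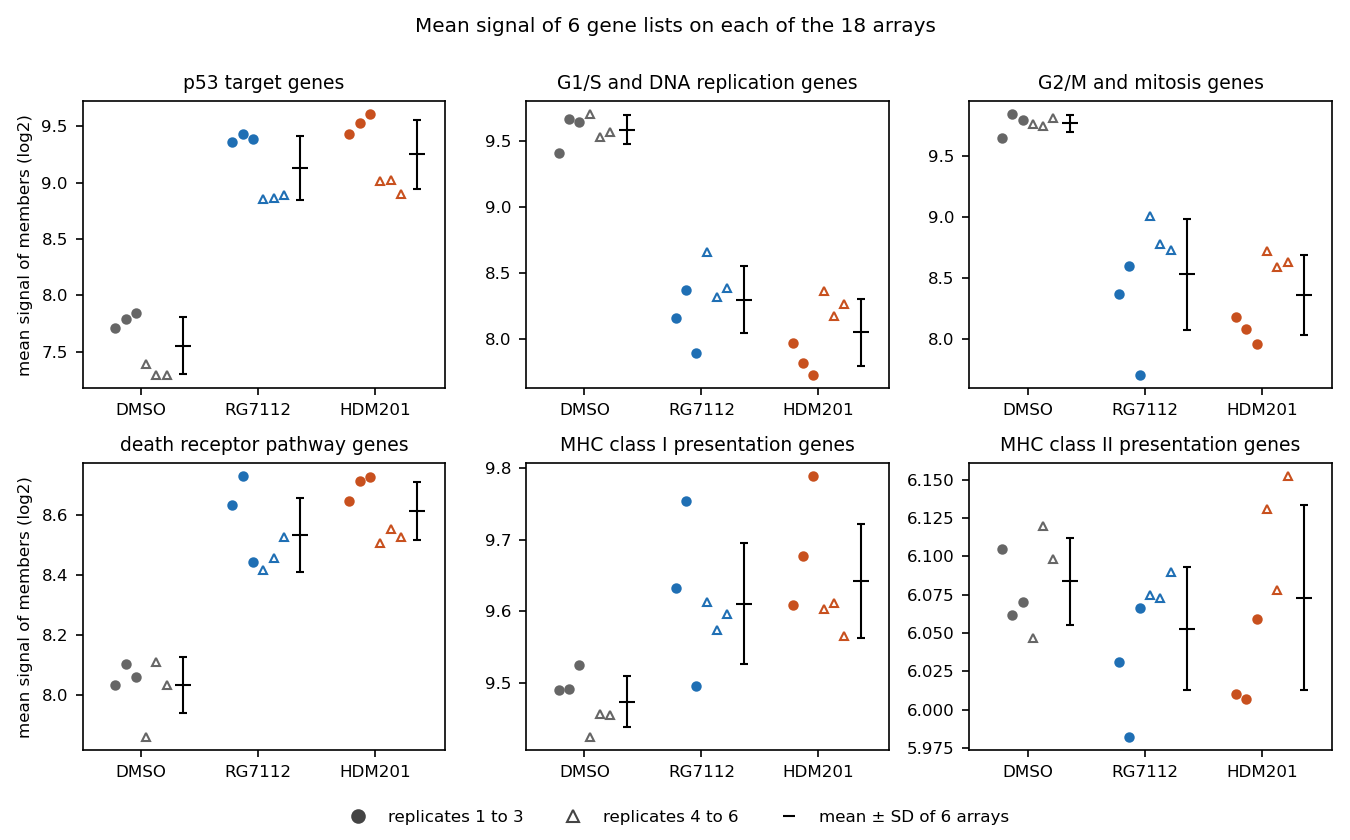
Mean log2 signal of the measured members of 6 gene lists on each of the 18 arrays by group, with filled circles for replicates 1 to 3, open triangles for replicates 4 to 6, and a bar for the mean and SD of 6 arrays. The p53 list lies at 7.56 under DMSO, 9.13 under RG7112 and 9.25 under HDM201, the G1/S list at 9.59, 8.30 and 8.05, and the MHC class II list at 6.08, 6.05 and 6.07.

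Ligands that T and NK cells recognise changed in both directions. TNFSF4, the ligand of OX40, rose 5.33-fold (2.41 ± 0.39, adjusted p = 1.62e-04), TNFSF9, the ligand of 4-1BB, 2.21-fold, and LGALS9, which encodes galectin-9, 2.41-fold, while ULBP3, a ligand of the activating receptor NKG2D, fell 1.66-fold. CD274, which encodes the inhibitory ligand PD-L1, differed by 0.02 ± 0.09 (adjusted p = 0.933) at a DMSO mean of 3.23. Of 28 measured members 7 rose, 3 fell and 18 did not pass, with equal counts when adjusted over the list alone, and the list mean of 0.19 (0.24 and 0.14 within the sets) did not pass (adjusted p = 0.197). Among 28 interferon response genes 1 rose, 9 fell and 18 did not pass (1 up and 10 down when adjusted over the list alone). USP18, a brake on interferon signalling, fell 2.72-fold, OAS1, a sensor of double-stranded RNA, 2.41-fold, and MX1, an antiviral GTPase, 2.24-fold, whereas TRIM22, which is also on the p53 list, rose 3.23-fold. The interferon list mean was -0.31 (-0.34 and -0.27 within the sets, adjusted p = 3.11e-04), with adjusted p = 0.100 with an estimated correlation. Without the probes below the median signal the mean was -0.08 (0.547), but that filter uses the mean over all arrays, which a fall itself lowers, so it does not show which members carry the shift. On this list too DMSO replicate 4 lay below the other DMSO arrays (6.29 against 6.49 to 6.59). Of 19 NF-kB and inflammatory cytokine genes 2 rose, 1 fell and 16 did not pass, also when adjusted over the list alone. CSF1, the macrophage growth factor, rose 6.34-fold and the chemokine CXCL8 1.98-fold, and the chemokine CCL2 fell 2.03-fold. CXCL8 no longer passed without DMSO replicates 2, 4 or 6 or RG7112 replicates 1, 3 or 5 (adjusted p from 0.0507 to 0.0713). The cytokine list mean was 0.21 (0.25 and 0.17 within the sets, adjusted p = 0.182).

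Several monocyte genes rose. ITGAM, the integrin chain CD11b, rose 4.25-fold (2.09 ± 0.32, adjusted p = 9.29e-05; 2.69 and 1.48 within the sets), S100A8 and S100A9, which form calprotectin, 2.95-fold and 2.37-fold, and CEBPB, a myeloid transcription factor, 2.00-fold. Of 23 measured monocyte and macrophage genes 6 rose, none fell and 17 did not pass (7 up when adjusted over the list alone). Over the monocyte list the mean was 0.39 (0.38 and 0.40 within the sets, adjusted p = 0.00208), a call lost at adjusted p = 0.170 with an estimated correlation, and DMSO replicate 1 lay above the other DMSO arrays (8.14 against 7.82 to 7.93). Of 12 granule and immature myeloid genes AZU1, a neutrophil granule protein, rose by 0.79 ± 0.07, FLT3, a receptor of myeloid progenitors, fell 2.26-fold, and 10 did not pass, also when adjusted over the list alone. The mean of that list was -0.03 (-0.10 and 0.03 within the sets), its median 0.03 and its test pointed up without passing (adjusted p = 0.698). Of 6 HOX and MEIS1 programme genes only PBX3, a partner of HOX proteins, passed, and fell 1.56-fold, with 2 down when adjusted over the list alone. PBX3 lay at 6.04 on RG7112 replicate 3 and 7.15 to 7.48 on the other RG7112 arrays. The HOX list mean was -0.14 (-0.20 and -0.09 within the sets, adjusted p = 0.331).

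Growth and metabolic lists shifted by smaller amounts. MYC, a transcription factor of cell growth, fell 1.46-fold (-0.54 ± 0.15, adjusted p = 0.0156; -0.77 and -0.32 within the sets). Of 19 MYC and ribosome biogenesis genes 6 fell, none rose and 13 did not pass (8 down when adjusted over the list alone), with a mean of -0.26 (-0.37 and -0.16 within the sets, adjusted p = 0.00158; adjusted p = 0.437 with an estimated correlation). Of 16 cholesterol synthesis genes 8 fell and 8 did not pass (10 down and 1 up when adjusted over the list alone), among them SQLE, an early sterol enzyme, 1.59-fold, and FDPS, which makes farnesyl diphosphate, 1.45-fold. That list mean was -0.30 (-0.19 and -0.41 within the sets, adjusted p = 5.36e-04), with adjusted p = 0.213 with an estimated correlation and 0.0595 within replicates 1 to 3 alone. Of 19 glycolysis genes 5 fell, 1 rose and 13 did not pass (9 down and 1 up when adjusted over the list alone). PFKFB3, which makes an activator of phosphofructokinase, rose 2.45-fold, and PFKP, a phosphofructokinase, fell by 0.56 on the log2 scale. The glycolysis mean was -0.23 in both sets (adjusted p = 0.00864), with adjusted p = 0.453 with an estimated correlation and 0.103 without the probes below the median signal.

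Stress genes moved apart. SLC7A11, the cystine transporter, rose 6.97-fold (2.80 ± 0.19, adjusted p = 4.95e-09) and SESN2, a stress sensor that p53 also induces, 2.89-fold, while PHGDH, the first enzyme of serine synthesis, fell by 2.39 ± 0.27 on the log2 scale (adjusted p = 2.78e-06) and ALDH1L2, a mitochondrial folate enzyme, fell 2.52-fold. Of 19 integrated stress response genes 6 rose, 5 fell and 8 did not pass (7 up and 7 down when adjusted over the list alone). The list mean was 0.05 (0.09 and 0.01 within the sets), the median -0.09 and the test pointed down without passing (adjusted p = 0.698). Of 14 heat shock and chaperone genes 5 fell, 1 rose and 8 did not pass (7 down and 2 up when adjusted over the list alone). HSPA4L rose 1.66-fold and HSPH1 fell by 0.45 ± 0.10 on the log2 scale, and both encode relatives of the HSP70 chaperones. This list, at a mean of -0.15 (-0.18 and -0.13 within the sets), passed at adjusted p = 0.0268 but gave adjusted p = 0.453 with an estimated correlation. It was also lost without DMSO replicate 2 (0.0646), DMSO replicate 3 (0.0653) or RG7112 replicate 5 (0.0688), without the probes in the lowest quartile of signal (0.0635), and within replicates 1 to 3 (0.0595) or 4 to 6 (0.0957) alone.

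Markers of other cell types gave few changes. Of 16 lymphocyte markers only CD79B, a chain of the B cell receptor, passed, rising 1.33-fold, and none passed when adjusted over the list alone. Among the fits with 1 array left out, CD79B passed only without DMSO replicates 1 or 5, RG7112 replicates 2, 4 or 6, or HDM201 replicates 3, 4 or 5. It was lost without any 1 of the other arrays and in 5 other settings with 5 or more arrays per group (adjusted p from 0.0502 to 0.0985). CD79B was also lost within replicates 4 to 6 alone (0.11, adjusted p = 0.669). The lymphocyte list mean was 0.03 (0.08 and -0.02 within the sets, adjusted p = 0.733). None of 12 erythroid and megakaryocyte markers passed, also when adjusted over the list alone, and their mean was 0.17 (0.24 and 0.09 within the sets, adjusted p = 0.0622), with RG7112 replicate 3 at 6.38 and the other RG7112 arrays at 5.93 to 6.06. That list passed without DMSO replicate 1 (0.0335), DMSO replicate 6 (0.0405), RG7112 replicate 1 (0.0446), RG7112 replicate 4 (0.0494) or RG7112 replicate 6 (0.0369), but without RG7112 replicate 3 the mean fell to 0.10 (adjusted p = 0.181), and with an estimated correlation the adjusted p was 0.453. Of 14 fibroblast and epithelial markers ACTA2, smooth muscle actin, rose by 1.85 ± 0.19, KRT8, a keratin, rose 1.36-fold and PECAM1, an adhesion molecule also found on leukocytes, fell 1.78-fold, with equal counts when adjusted over the list alone. KRT8 no longer passed without DMSO replicates 2, 3, 4 or 6 or RG7112 replicate 1 (adjusted p from 0.0521 to 0.0719), or with only the DMSO and RG7112 arrays in the model (0.0582). RG7112 replicate 3 lay apart from its group for ACTA2 (9.58 against 10.3 to 10.6), KRT8 (8.84 against 7.80 to 8.19) and PECAM1 (6.16 against 7.23 to 7.69). The list mean was 0.13 (0.07 and 0.19 within the sets, adjusted p = 0.405).

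Across the array RG7112 changed 3757 of 21448 probes at an adjusted p under 0.05 in limma, 1695 up and 2062 down, and 544 of them at least 2-fold (259 up and 285 down). Increases made up 45.1% of the calls, and 33.2% with each array's median subtracted. All 6 RG7112 arrays lay on 1 side of all 6 DMSO arrays for 2124 probes, 9.90% of all, where chance gives 0.217%. Within replicates 1 to 3 alone 1973 probes passed and within 4 to 6 alone 2148, with 1298 in both, 1297 of these in the same direction. Every pooled call had the same sign in both sets, which calling on the pooled arrays favours. Without RG7112 replicate 3 there were 3530 calls, 3175 of them among the 3757. Of the 22 lists 12 passed, 4 up and 8 down, and 3 with an estimated correlation. With 3 arrays per group, 21 of the 108 values of named genes no longer passed in replicates 1 to 3 and 20 in replicates 4 to 6. The 108 include genes that had not passed with all arrays, so the share lost among the calls is larger.

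HDM201 against DMSO asks the same question of the other MDM2 inhibitor. HDM201 raised CDKN1A 17.2-fold (4.10 ± 0.33, adjusted p = 2.27e-08; 3.66 within replicates 1 to 3 and 4.54 within 4 to 6) and MDM2 5.98-fold (2.58 ± 0.17, adjusted p = 2.73e-09; 2.28 and 2.89 within the sets). Of 40 p53 target genes 38 rose, none fell and 2 did not pass, also when adjusted over the list alone, among them CMBL at 16.5-fold, TP53INP1 at 10.9-fold, TP53I3 at 10.8-fold and BAX by 0.91 ± 0.10. PMAIP1 differed by 0.23 ± 0.14 (adjusted p = 0.309). The list mean was 1.70 (1.74 and 1.66 within the sets), with adjusted p = 2.15e-41 and adjusted p = 0.0397 with an estimated correlation. With the replicate sets added to that model the list gave adjusted p = 1.47e-06. MDM4 differed by 0.27 ± 0.11 (adjusted p = 0.114) and passed only without DMSO replicate 5 (0.0337) and with array weights (0.0474). The largest increases in signal were those of FCER1A at 37.2-fold (5.22 ± 0.54; 6.34 and 4.09 within the sets) and CLCA2 at 31.4-fold (4.97 ± 0.55; 6.23 and 3.72), both lower bounds from a DMSO signal near the bottom of the range, then ENPP2 at 18.5-fold and DLX5 at 14.7-fold. The difference between the sets passed for FCER1A (adjusted p = 0.00261) and CLCA2 (adjusted p = 0.00566).

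All 31 G1/S and DNA replication genes, all 30 G2/M and mitosis genes and 10 of 12 recombination and Fanconi genes fell under HDM201, with 1 recombination gene up and 1 not passed, also when adjusted over the lists alone. EXO1 fell 4.73-fold (-2.24 ± 0.17, adjusted p = 1.10e-08), CDC6, which licenses replication origins, 4.33-fold, CCNE2 4.29-fold, E2F1 4.14-fold (-2.05 ± 0.17, adjusted p = 4.63e-08; -2.37 and -1.73 within the sets) and GINS2 4.09-fold. TTK fell 3.36-fold, FOXM1, a transcription factor of mitotic genes, 3.12-fold (-1.64 ± 0.19), and MKI67 2.43-fold, with DMSO replicate 3 below the other DMSO arrays for MKI67 (11.1 against 11.3 to 11.4). The G1/S mean was -1.54 (-1.74 and -1.33 within the sets), with adjusted p = 8.61e-45 and adjusted p = 0.0397 with an estimated correlation. With the replicate sets added to that model the G1/S list gave adjusted p = 0.0186. The recombination list mean was -1.45 (-1.64 and -1.26 within the sets), with adjusted p = 2.08e-14 and adjusted p = 0.0397 with an estimated correlation. The G2/M mean was -1.40 (-1.68 and -1.12 within the sets, adjusted p = 3.89e-33), a call lost at adjusted p = 0.0647 with an estimated correlation and kept at 0.0441 with the replicate sets added to that model.

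Of the 17 MHC class I presentation genes 4 rose under HDM201, 1 fell and 12 did not pass (5 up and 1 down when adjusted over the list alone). TAP1 rose 2.85-fold (1.51 ± 0.14, adjusted p = 1.80e-07; 1.77 and 1.25 within the sets), and ERAP2, an aminopeptidase that trims peptides, 1.55-fold (0.64 ± 0.17, adjusted p = 0.00864). PSMB9 fell by 0.40 ± 0.12 on the log2 scale (adjusted p = 0.0278), a call lost without DMSO replicates 2 or 3 or HDM201 replicates 1, 2 or 3 (adjusted p from 0.0570 to 0.0638). HLA-C differed by 0.20 ± 0.07 (adjusted p = 0.0759) and passed without DMSO replicate 1 (0.0477), with array weights (0.0414) and without the probes below the median signal (0.0394), and B2M by 0.13 ± 0.07 (adjusted p = 0.270). The class I list mean was 0.17 (0.19 and 0.15 within the sets, adjusted p = 0.116). Of 16 MHC class II presentation genes only RFX5, a factor at class II promoters, passed, at 1.23-fold up (adjusted p = 0.0217), and none passed when adjusted over the list alone. RFX5 no longer passed without DMSO replicates 1 or 5 or HDM201 replicates 4 or 5 (adjusted p from 0.0506 to 0.0539), or with each array's median subtracted (0.0742). HLA-DRA differed by -0.01 ± 0.09 (adjusted p = 0.951), with DMSO replicate 5 at 4.10 and the other DMSO arrays at 3.61 to 3.74, CD74 by -0.01 ± 0.18 (0.985) and CIITA by -0.19 ± 0.16 (0.486). The class II list mean was -0.01 (-0.05 and 0.03 within the sets), its median 0.03 and its test pointed up without passing (adjusted p = 0.812).

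Of the 13 death receptor pathway genes 8 rose under HDM201, none fell and 5 did not pass, also when adjusted over the list alone. TNFRSF10B rose 3.38-fold (1.76 ± 0.13, adjusted p = 6.06e-09; 1.76 in both sets), FAS 2.88-fold (1.52 ± 0.22, adjusted p = 3.31e-05; 1.63 and 1.42 within the sets), TNFRSF10A 2.50-fold (1.32 ± 0.12, adjusted p = 8.04e-08; 1.5 and 1.15 within the sets) and TNFRSF10D 2.22-fold. Over the death receptor list the mean was 0.58 (0.63 and 0.53 within the sets), with adjusted p = 2.08e-05 and adjusted p = 0.0484 with an estimated correlation, and DMSO replicate 4 lay below the other DMSO arrays (7.86 against 8.03 to 8.11). In the BCL2 family 5 of 16 genes rose, 1 fell and 10 did not pass, also when adjusted over the list alone, with BCL2A1 up 3.07-fold and BAK1 1.57-fold. The family mean was 0.28 (0.37 and 0.19 within the sets, adjusted p = 0.0135; adjusted p = 0.272 with an estimated correlation), and the call was lost within replicates 4 to 6 alone (0.138). Of 28 T and NK cell ligand genes 7 rose, 3 fell and 18 did not pass, also when adjusted over the list alone. TNFSF4 rose 6.02-fold (2.59 ± 0.39, adjusted p = 5.26e-05), LGALS9 3.19-fold, TNFSF9 2.18-fold and ICOSLG, the ligand of ICOS, 1.63-fold, while CD274 differed by 0.08 ± 0.09 (adjusted p = 0.654). This list had a mean of 0.25 (0.31 and 0.18 within the sets, adjusted p = 0.116).

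Of 28 interferon response genes 8 fell under HDM201, TRIM22 rose 3.37-fold and 19 did not pass (11 down and 2 up when adjusted over the list alone). USP18 fell 2.94-fold, OAS1 2.47-fold and OAS2, another sensor of double-stranded RNA, 2.31-fold, with OAS2 at 6.25 on HDM201 replicate 5 and 5.30 to 5.65 on the other HDM201 arrays. The interferon mean was -0.27 (-0.33 and -0.21 within the sets, adjusted p = 0.00299), with adjusted p = 0.190 with an estimated correlation. Without the probes below the median signal the mean was -0.02 (0.714), with the same limit of that filter. DMSO replicate 4 lay below the other DMSO arrays on this list (6.29 against 6.49 to 6.59). Of 19 NF-kB and inflammatory cytokine genes CSF1 (9.09-fold), CXCL8 and IL1B, a cytokine of myeloid cells (1.78-fold), rose and 16 did not pass, also when adjusted over the list alone. The CXCL8 call (0.0208) was lost without DMSO replicate 4 (0.0624) or HDM201 replicate 1 (0.0615). The cytokine list had a mean of 0.27 (0.35 and 0.19 within the sets, adjusted p = 0.194).

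Of 23 monocyte and macrophage genes 7 rose under HDM201 and 16 did not pass (11 up and 1 down when adjusted over the list alone). ITGAM rose 4.52-fold (2.18 ± 0.32, adjusted p = 4.03e-05; 2.94 and 1.41 within the sets), S100A8 3.99-fold, S100A9 2.85-fold and CEBPB 2.03-fold. The list mean of 0.47 (0.47 in both sets) passed at adjusted p = 8.66e-04, with adjusted p = 0.138 with an estimated correlation, and DMSO replicate 1 lay above the other DMSO arrays (8.14 against 7.82 to 7.93). Of 12 granule and immature myeloid genes AZU1 rose by 0.91 ± 0.07, FLT3 fell 2.31-fold and PRTN3, a granule protease, fell 1.33-fold, with equal counts when adjusted over the list alone. The PRTN3 call was lost without DMSO replicates 2, 3 or 6 or HDM201 replicates 1 or 2 (adjusted p from 0.0530 to 0.0877). The granule list mean was -0.04 (-0.10 and 0.02 within the sets), the median 0.02 and the test pointed up without passing (adjusted p = 0.812). Of 6 HOX and MEIS1 programme genes PBX3 fell 1.46-fold (2 down when adjusted over the list alone), with HDM201 replicate 5 at 7.63 and the other HDM201 arrays at 7.05 to 7.26. That call was lost without DMSO replicates 2, 4, 5 or 6 or HDM201 replicates 1, 2, 3, 4 or 6 (adjusted p from 0.0547 to 0.0867) and after a further quantile normalization (0.0538), and the HOX list mean was -0.12 (-0.13 and -0.11 within the sets, adjusted p = 0.464).

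MYC fell 1.47-fold under HDM201 (-0.55 ± 0.15, adjusted p = 0.0124; -0.75 and -0.36 within the sets), 1 of 7 MYC and ribosome biogenesis genes that fell, while none rose and 12 did not pass (9 down when adjusted over the list alone). That list mean was -0.29 (-0.42 and -0.15 within the sets, adjusted p = 4.72e-04; adjusted p = 0.380 with an estimated correlation). Of 16 cholesterol synthesis genes 3 fell, 1 rose and 12 did not pass (7 down and 1 up when adjusted over the list alone), and FDPS fell by 0.59 on the log2 scale and SQLE 1.56-fold. The cholesterol mean was -0.19 (-0.11 and -0.27 within the sets, adjusted p = 0.0476; adjusted p = 0.502 with an estimated correlation). It was lost without DMSO replicates 1, 5 or 6, RG7112 replicates 3 or 4 or HDM201 replicates 2 or 6 (adjusted p from 0.0518 to 0.112), within replicates 1 to 3 alone (0.274), without the probes in the lowest quartile of signal (0.0945) or below its median (0.156), with each array's median subtracted (0.0528), and with only the DMSO and HDM201 arrays in the model (0.0537). Of 19 glycolysis genes 6 fell, 1 rose and 12 did not pass (10 down and 1 up when adjusted over the list alone). PFKFB3 rose 2.57-fold and PFKP fell by 0.67 on the log2 scale. The glycolysis mean was -0.24 (-0.25 and -0.23 within the sets, adjusted p = 0.00659), with adjusted p = 0.537 with an estimated correlation and 0.0575 without the probes below the median signal.

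SLC7A11 rose 6.69-fold and SESN2 3.34-fold under HDM201, and PHGDH fell 6.12-fold (-2.61 ± 0.27, adjusted p = 5.11e-07) and ALDH1L2 2.51-fold. Of 19 integrated stress response genes 6 rose, 6 fell and 7 did not pass (7 up and 6 down when adjusted over the list alone), with a mean of 0.09 (0.11 and 0.07 within the sets), a median of -0.09 and a test that pointed down without passing (adjusted p = 0.812). Of 14 heat shock and chaperone genes 5 fell, HSPA4L rose 1.91-fold and 8 did not pass (7 down and 2 up when adjusted over the list alone). HSPH1 fell by 0.43 ± 0.10 on the log2 scale, with HDM201 replicate 4 at 11.4 and the other HDM201 arrays at 11.1 to 11.2. The heat shock mean of -0.12 (-0.15 and -0.09 within the sets) passed at adjusted p = 0.0476 but gave adjusted p = 0.567 with an estimated correlation. The call was lost without DMSO replicates 2, 3 or 4, RG7112 replicate 4 or HDM201 replicates 1, 2, 5 or 6 (adjusted p from 0.0518 to 0.114), and in 8 further settings (adjusted p from 0.0524 to 0.256).

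None of the 16 lymphocyte and 12 erythroid and megakaryocyte markers passed under HDM201, also when adjusted over the lists alone, and their means were 0.04 (0.13 and -0.05 within the sets, adjusted p = 0.741) and 0.08 (0.15 and 0.02 within the sets, adjusted p = 0.464). Without RG7112 replicate 3 the lymphocyte marker CD79B (0.0418) and HBA1, a chain of haemoglobin (0.0287), passed, and CD79B also with array weights (0.0324) and with only the DMSO and HDM201 arrays in the model (0.0239). Of 14 fibroblast and epithelial markers ACTA2 rose 4.32-fold, PECAM1 fell 1.90-fold and EPCAM, an epithelial adhesion molecule, fell 1.32-fold from a DMSO mean of 4.32, with equal counts when adjusted over the list alone. Their mean was 0.11 (0.03 and 0.19 within the sets, adjusted p = 0.741).

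HDM201 changed 4032 of 21448 probes in limma, 1965 up and 2067 down, and 695 of them at least 2-fold (329 up and 366 down). Increases made up 48.7% of the calls, and 41.4% with each array's median subtracted. All HDM201 arrays lay on 1 side of all DMSO arrays for 2907 probes, where chance gives 0.217% of the probes. Within replicates 1 to 3 alone 2504 probes passed and within 4 to 6 alone 2595, with 1669 in both, all in the same direction. Every pooled call had the same sign in both sets, which calling on the pooled arrays favours. Without RG7112 replicate 3, which enters the shared estimate of the spread, 5212 probes passed, all 4032 among them. Of the 22 lists 12 passed, 4 up and 8 down, and 4 with an estimated correlation. With 3 arrays per group, 11 of the 106 values of named genes no longer passed in replicates 1 to 3 and 17 in replicates 4 to 6. Here too the 106 include genes that had not passed with all arrays, so the share lost among the calls is larger.

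The compounds were then set against each other, at 2 µM for RG7112 and 500 nM for HDM201, so that dose and compound differ together. No probe differed in limma (0 of 21448), and 749 passed at an unadjusted p under 0.05 where chance gives 1072. The smallest adjusted p was 0.758, and without HDM201 replicate 6 a single probe passed. The 95% interval of the difference lay within 1 log2 unit of zero for 99.7% of the probes and within 0.5 for 89.5%. MDM2 differed by 0.01 (95% interval -0.35 to 0.36), CDKN1A by 0.14 (-0.55 to 0.82), TNFRSF10A by 0.13 (-0.12 to 0.38), TNFRSF10B by 0.12 (-0.14 to 0.39), FAS by 0.08 (-0.39 to 0.54), HLA-DRA by 0.04 (-0.16 to 0.23) and CD274 by 0.06 (-0.13 to 0.25). The model behind these intervals has no term for the replicate sets, so they include the spread between the sets. The members of the G1/S and recombination lists with the largest differences were CDC45, a part of the replicative helicase, at -0.50 (-0.75 to -0.25), and EXO1 at -0.59 (-0.94 to -0.23), and neither passed after adjustment over all probes. When adjusted over the list alone 3 of 31 G1/S genes and 3 of 12 recombination genes were lower under HDM201.

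In the list test with a preset correlation 5 of 22 lists differed between the compounds, 2 higher and 3 lower under HDM201, and 0 with an estimated correlation. The G1/S list differed by -0.25 (-0.31 and -0.19 within the sets, adjusted p = 6.79e-17; adjusted p = 0.692 with an estimated correlation), the recombination list by -0.23 (-0.24 and -0.21, adjusted p = 1.36e-05; 0.692), the G2/M list by -0.17 (-0.15 and -0.19, adjusted p = 4.31e-06; 0.799), the p53 list by 0.12 (0.13 and 0.11, adjusted p = 0.00828; 0.799) and the cholesterol list by 0.11 (0.09 and 0.14, adjusted p = 0.00218; 0.692). The p53 call was lost without RG7112 replicates 4, 5 or 6 or HDM201 replicates 1, 2 or 3 (adjusted p from 0.125 to 0.614) and without the probes below the median signal (0.148), the G2/M call without RG7112 replicate 4 (0.0666), and the cholesterol call within replicates 1 to 3 alone (0.328). Leaving out 1 array moved the p53 difference between 0.05 and 0.19 and the G2/M difference between -0.08 and -0.34, the latter without RG7112 replicate 3. Leaving out 1 array makes the replicate sets unequal, and the p53 list differed between the sets by 0.52 and 0.54 under the compounds. With the set as a block the p53 call stood (adjusted p = 1.16e-05), as did the G2/M call (3.01e-08), but neither stood with the set block and an estimated correlation (0.147 and 0.656). Among the lists that did not pass, the death receptor list (0.08, adjusted p = 0.0708) passed without RG7112 replicate 1 (0.0458), RG7112 replicate 2 (0.0217), HDM201 replicate 4 (0.0290) or HDM201 replicate 6 (0.0482), with the set as a block (0.0462), with only the 12 arrays compared (0.0483) and without the probes in the lowest 25% of signal (0.0408), and the erythroid list (-0.08, adjusted p = 0.0551) without DMSO replicate 2, RG7112 replicates 1, 2, 4 or 6 or HDM201 replicates 1, 2 or 3 (from 0.0120 to 0.0485), with only the 12 arrays compared (0.0483) and without the probes in the lowest 25% of signal (0.0300). Without RG7112 replicate 3 the erythroid difference was -0.02 (adjusted p = 0.852), so it rests mostly on that array. The MYC list (-0.02, adjusted p = 0.428) passed without RG7112 replicate 3 (0.0045, and 0.01075 with the set as a block) or HDM201 replicate 4 (0.0396), but its difference ran from -0.08 to 0.02 when single arrays were left out, and the monocyte list (0.08, adjusted p = 0.428) without RG7112 replicate 1 (0.0458). The remaining lists gave adjusted p from 0.428 to 0.997. The mean and median differed in sign for the MHC class II list (0.02 and -0.03, test down) and the lymphocyte list (0.01 and -0.01, test up).

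The mean of each list per array was also compared by an exact permutation test, two-sided, where 6 against 6 arrays give 924 permutations and no p below 0.00217. None of the 22 lists passed after adjustment. The cholesterol synthesis list had the smallest value, with a difference of 0.11 (95% interval 0.02 to 0.20, exact p = 0.0195, adjusted p = 0.429), and passed only without HDM201 replicate 2 (adjusted p = 0.0476). The p53 list score differed by 0.12 (-0.25 to 0.49, exact p = 0.513), the G1/S score by -0.25 (-0.57 to 0.08, exact p = 0.121), the G2/M score by -0.17 (-0.65 to 0.36, exact p = 0.457) and the recombination score by -0.23 (-0.55 to 0.12, exact p = 0.171). These p-values and intervals include the spread between the replicate sets. With permutations within the sets, a test chosen after the sets were seen, p was 0.01 for the p53 score, 0.03 for the G1/S and cholesterol scores, 0.075 for the recombination score and 0.24 for the G2/M score, and the smallest adjusted p over the 22 lists was 0.22. The MHC class I score differed by 0.03 (-0.07 to 0.14, exact p = 0.513), the class II score by 0.02 (-0.05 to 0.09, exact p = 0.513) and the death receptor score by 0.08 (-0.07 to 0.23, exact p = 0.247). Neither these intervals nor the missing calls show that the compounds act alike.

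The changes under the compounds ran together across probes. The correlation of the log2 changes against DMSO was 0.949 (Spearman's rho 0.849) over 21448 probes, which are not independent replicates. Unchanged groups simulated against the same DMSO arrays gave a mean correlation of 0.494 (0.0188 to 0.855) and rho of 0.473. These groups were drawn without regard to the replicate sets, which the real groups hold in equal numbers. The simulated values therefore include imbalance that the real groups lack. With different DMSO arrays on each side the observed correlation was 0.871 (0.809 to 0.899). Fewer controls, with the sets unequal between the sides, also lower that value. The covariance was 0.130 against a simulated 0.00945, a difference of 0.121. The slope of the HDM201 changes on the RG7112 changes was 1.08, with a jackknife standard error of 0.17 and a range of 1.01 to 1.18 when single arrays were left out. Both compounds raised 1393 probes and lowered 1699, with 0 in opposite directions. Independent lists of those sizes would share 155.3 and 198.7, simulated unchanged groups shared 0, and separate DMSO arrays left means of 746.4 and 942.6. The separate controls hold fewer arrays, which by itself lowers the number of calls, so this drop does not measure the part due to sharing. Among the 4697 probes called under either compound 68.1% had the larger change under HDM201, and among all 21448 probes 50.2%. HDM201 gave more of the calls, which favours it in the share among called probes.

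**Figure D3:**
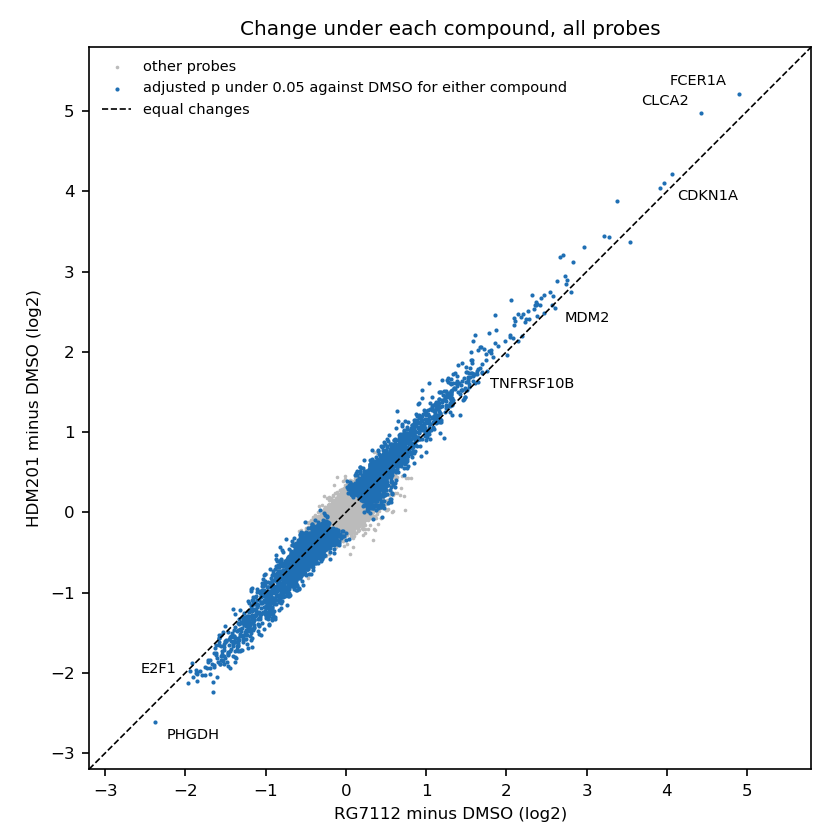
Log2 change under HDM201 against log2 change under RG7112, both relative to DMSO, for all 21448 probes, with blue for probes called under either compound (4697) and a dashed line where both changes are equal. The points follow a slope of 1.08, and the largest difference between the compounds at any probe is 0.71 on the log2 scale.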

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

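The replicate sets were seen in the data, and the tests between the sets and the count of marker genes in the test for cells of another type were chosen after the results had been seen, while the other tests of this part were set before. For each group of 6 arrays, the gap between the most extreme array and its nearest neighbour was divided by the range of the group and compared with Dixon's 95% limit. Of 504 such tests on named genes, gene lists and array measures 34 passed the limit, where chance gives about 1 in 20, that is 25.2. Of the 34, 19 concern RG7112 replicate 3.

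RG7112 replicate 3 stood apart in its mean correlation with its own group (gap share 0.886; 0.972 against 0.986 to 0.988) and in the erythroid and megakaryocyte marker list (0.721; 6.38 against 5.93 to 6.06). It was low in the cell cycle genes SGO1 (0.816; 5.58 against 7.42 to 7.83), E2F8 (0.770) and CDC25C (0.679), and in FANCI of the Fanconi pathway (0.653). It was also low in CD180, a surface protein of B cells and monocytes (0.680; 3.73 against 6.59 to 7.93), PBX3 (0.772), ACTA2 (0.739), PECAM1 (0.698), DHCR7 (0.747), LDHA (0.685), NOP58 (0.719), NOLC1 (0.655) and BID (0.648). It was high in HBA1, a chain of haemoglobin (0.841; 7.99 against 7.25 to 7.37), BCL2L2 (0.795), BAX (0.726) and KRT8 (0.634).

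The other 15 cases lie on 10 different arrays. RG7112 replicate 2 was high in XIAP (0.690) and ERAP2 (0.653), and RG7112 replicate 5 in PAX5 (0.654). Among the DMSO arrays, replicate 5 was high in HLA-DRA (0.746; 4.10 against 3.61 to 3.74), replicate 3 low in MKI67 (0.638) and HOXB6 (0.649), and replicate 6 high in SC5D (0.661). DMSO replicate 4 was low in the death receptor list (0.687; 7.86 against 8.03 to 8.11) and the interferon list (0.667), and DMSO replicate 1 high in the monocyte list (0.665). Among the HDM201 arrays, replicate 5 was low in DDIT3 (0.739) and high in PBX3 (0.647) and OAS2 (0.626), replicate 4 high in HSPH1 (0.655), and replicate 3 low in HBB (0.647). The cause of these was not tested.

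The effects of the compounds differed between the replicate sets for some genes, by a test of the difference itself (the term for set and treatment in limma). The RG7112 effect differed for 8 probes (1309 at an unadjusted p under 0.05) and the HDM201 effect for 32 (1315), where chance gives 1072 at that unadjusted p. FCER1A (4 to 6 minus 1 to 3: -2.19, adjusted p = 0.00744 for RG7112; -2.24, adjusted p = 0.00261 for HDM201), CLCA2 (-2.43 and -2.51) and TP53I3 (-0.92 and -0.90) rose more in replicates 1 to 3. The log2 differences of THBS1, DSEL, PLTP, ARRDC2 and ZNF561, chosen here after their values were seen, were also larger there under both compounds. In all, the term was negative (4 to 6 minus 1 to 3) for the 8 probes under RG7112. Under HDM201 it was negative for 27 of the 32 and positive for 5. Among the 5 were NUF2 (0.98), PLK4 (1.198), TCN1 (1.28) and APOBEC3H (1.23), also chosen after their values were seen. TCN1 and APOBEC3H already differed between the DMSO sets, by -1.63 and -1.255 (4 to 6 minus 1 to 3). Their terms are of similar size and opposite sign, so they need not mark a different response. The labels give no difference between the sets, so no biological explanation was tested.

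RG7112 replicate 3 also deviated from its group over all probes, with an SD of 0.502 against 0.184 to 0.288 on the other arrays. A narrower signal range as the whole cause is argued against, since 0.468 was left after a trend with signal level was removed, above 0.184 to 0.272 on the other arrays. A stronger response to the compound as the whole cause is argued against as well, since 0.480 was left after the part proportional to the HDM201 change was removed, above 0.182 to 0.285. As a part of the cause it stays open, since the G2/M list stood at percentile 0 of random lists on that array (mean deviation -0.99), the recombination list at 0.06 and the G1/S list at 0.23. The p53 list stood at percentile 100 (0.30), but these deviations are from the mean of all other RG7112 arrays, of both replicate sets. Against RG7112 replicates 1 and 2 the p53 list was not raised (9.39 against 9.36 and 9.43), while the G2/M list was lower (7.71 against 8.37 and 8.60). The p53 percentile is therefore no sign of a stronger response. Cells of another type in that sample could raise the erythroid and megakaryocyte markers and remain open. That list stood at percentile 99.6 of random lists, and 8 of its 12 measured members lay above every other RG7112 array, as did 29.0% of all genes. HBA1 and ITGA2B (7.57 against 5.98 to 6.58) were among the 8, while HBB (5.31 against 4.82 to 5.67), PF4 (6.74 against 6.40 to 6.75), ALAS2 and GATA1 lay inside the range, so the members moved apart and none of them decides. RNA quality and hybridisation of that array were not tested and remain open, and the labels name no biological difference.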

How the results depend on the processing

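The settings that use the replicate sets (the set as a block, with or without the third RG7112 array, each set alone, and the estimated correlation with the set as a block) were chosen after seeing the data. No value changed direction past its threshold. Over all settings and values 9808 stayed on their side of the threshold or near the reported value, 353 no longer passed, 209 passed in addition and 13 moved.

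With 3 arrays per group fewer probes pass: 1973 (only replicates 1 to 3) and 2148 (only replicates 4 to 6) for RG7112, where all arrays gave 3757, and 2504 and 2595 for HDM201, where they gave 4032. For the lists the estimated correlation decides most. With it 3 lists passed for RG7112, 4 for HDM201 and 0 between the compounds, and with the set block added 2, 5 and 0, where the preset correlation gave 12, 12 and 5. For the p53 list the estimated correlation is 0.609, against the preset 0.01, which widens its test. That estimate comes from the model without the replicate sets. With the set block added the p53 list gave adjusted p = 1.38e-06 for RG7112 and 1.47e-06 for HDM201.

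Leaving out 1 array at a time gave 3074 (without DMSO replicate 6) to 4085 (without RG7112 replicate 4) probes for RG7112 and 3374 (without HDM201 replicate 2) to 5212 (without RG7112 replicate 3) for HDM201. Between the compounds it gave 0 to 1 probes (1 without HDM201 replicate 6), 4 lists (without RG7112 replicates 4 or 5) to 8 (without RG7112 replicate 1), and 0 to 1 list scores (1 without HDM201 replicate 2). The cause was not tested. The slope between the compounds was 1.196 with array weights, and between 1.01 and 1.18 without single arrays. The other settings kept the counts of changed probes against DMSO within 1.5 times, from 3164 with only the 12 arrays compared to 5798 with the set block and without RG7112 replicate 3.

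With the replicate block 4780 probes passed for RG7112, 4866 for HDM201 and 0 between the compounds. MDM4 (adjusted p = 0.0383) under RG7112 and the death receptor list between the compounds (0.0467) passed with it, and CIITA under RG7112 (0.0565) did not, while the list scores gave adjusted p of 0.229 or more. Without the block but with an estimated correlation, that death receptor comparison gave adjusted p = 0.799. As a hint from the data, 16 of 18 correlations between same-numbered arrays of different groups exceeded 0.1 (0.017 to 0.440), and in 12 of the 18 the best match was the own number and in 17 a number of the own set. This may point to handling by number as well as by set, but the records do not state pairs, so the main fit has no block. Genes with a signal near the lower end of the arrays, such as HLA-DRA and CD274, limit what small differences can be seen.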

Other observations

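The tests between the replicate sets were chosen after the sets had been seen, as were the comparison of the DMSO sets with random lists and the tests within the sets or by number, while the other tests in this part were set before their results were seen.

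DMSO cells of replicates 1 to 3 and of 4 to 6 differed in 65 probes in limma (n = 3 arrays per set, 1257 at an unadjusted p under 0.05, where chance gives 1072). Higher in replicates 1 to 3 were the p53 targets CDKN1A (9.06 against 7.40), MDM2 (10.33 against 9.44), TP53INP1 (difference 1.01), XPC (0.85), RPS27L (0.83), SESN1 (0.69) and TRIM22 (1.01), and the myeloid genes S100A9 (1.34) and SERPINB10 (2.06). Lower were CACHD1 (2.08), the amino acid transporter SLC7A2 (1.89), the small GTPase RRAS2 and the NKG2D ligand ULBP3 (0.78). Of these XPC, RPS27L, SESN1, SERPINB10, CACHD1, SLC7A2 and RRAS2 were chosen after their values were seen. As a list the p53 targets were higher in replicates 1 to 3 (adjusted p = 6.96e-25 by camera at the preset correlation), with no overlap between the arrays of the sets. At that correlation the cholesterol synthesis and glycolysis lists also passed, as lower (adjusted p = 8.00e-05 for both), but their array means overlapped between the sets (-0.229 with an SD of 0.172 inside the sets and -0.257 with an SD of 0.246), and the other lists gave adjusted p of 0.0784 or more. The glycolysis list split by other numbers, with replicates 1, 5 and 6 above 2, 3 and 4 in every group. The ranges were 10.64 to 10.81 against 10.19 to 10.35 under DMSO and 10.33 to 10.54 against 9.91 to 10.25 under RG7112. Under HDM201 they were 10.25 to 10.59 against 10.01 to 10.19. The cholesterol list split in this way under DMSO only. This split was seen after the fact, and its cause was not tested. The p53 list differed between the sets by 0.45 under DMSO, 0.52 under RG7112 and 0.54 under HDM201.

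A signal difference of the whole array is argued against as the cause of the higher p53 list in DMSO replicates 1 to 3: the list differed by 0.454, where random lists of equal level gave a median of 0.008 and an upper bound of 0.062. RNA of treated cells mixed into those samples is argued against. Probes outside the p53 list that both compounds raised at least 4-fold (29 of 40) differed by a median of 0.20, where the mixture needed for the list predicts 0.601, and the median shortfall was -0.486 (95% interval -0.607 to -0.207). That interval comes from resampling these probes, so it measures the spread between genes and not between arrays. The mixture of 5.83% is the median over 11 list members, which ran from -0.17% to 15.1%. Partial activation of p53 in those cultures remains open: it could lower the G1/S list, and that list differed by -0.024, within an SD of 0.119 inside the sets. The 10 splits of the replicate numbers into equal parts are too few for a share under 0.05. Only 1 split, the one by set, gave as many as 1712 probes. The split of numbers 1, 5 and 6 from 2, 3 and 4 gave 202, and each of the rest gave 0.

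In the list test at the preset correlation, changes under HDM201 exceeded those under RG7112 in the p53 and G1/S lists. With an estimated correlation neither list passed (adjusted p = 0.799 and 0.692), and the list scores gave exact p of 0.513 and 0.121 by permutation. RG7112 replicate 3 does not account for the G1/S difference, since without it that difference was -0.328, against -0.247 with all arrays, and -0.306 with the set as a block. A larger response at the HDM201 dose used may contribute and stays open, since dose and compound differ together. The p53 minus G1/S score was 1.2 for HDM201 and 0.834 for RG7112, a difference of 0.367 (95% interval -0.331 to 1.051, exact p = 0.247, two-sided permutation test), where the mean change against DMSO was 3.05. The difference was 0.434 within replicates 1 to 3 and 0.30 within 4 to 6, and with permutations within the sets p was 0.01. Between arrays of the same number the score was higher under HDM201 in all 6 cases (p = 0.0313, exact sign-flip test, the smallest that 6 pairs allow), which counts as a test only if the numbers pair the samples, and the labels do not say so.

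Of 100 splits of the 12 arrays into equal groups, the real split included, only 1, the real one, gave as many probes for RG7112 against DMSO (3164 with these 12 arrays, highest other 0), and only 1 for HDM201 against DMSO (5134, highest other 0). That is the smallest share that 100 splits can give, so chance is argued against for these counts but not excluded. The other splits put treated and DMSO arrays in the same group, which widens the spread and favours 0 calls. Between the compounds the real split gave 0 probes, a count that all 100 splits reach by construction (highest other 3), so the splits decide nothing there. Splitting the HDM201 and RG7112 arrays by replicate set gave 1430 probes. The sets were defined after these same arrays had been seen, so this count restates their difference and adds no separate support.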
